A study of Homo sapiens with 6 samples.

How the data were processed

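Polyadenylated RNA of H69 cells was sequenced as 6 libraries, 3 from vehicle-treated and 3 from TSA-treated cells, per the labels with a stranded messenger RNA kit on an Illumina instrument. The submitters' processing notes name FastQC 0.11.2, STAR 2.5.3a, Picard 1.127, featureCounts, edgeR and the human build hg19, and give no roles or order for them. The gene annotation is GENCODE 19, per the name of the deposited table. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense genes could not be told apart, and reads shared between near-identical copies make the values of such genes uncertain.

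The authors deposited expression as TPM, read counts scaled by gene length and library total, with 31814 genes and a column for each library that sums to the same total. The authors' deposited table of their own comparison gives a log2 fold change and a mean log2 level per gene, per the file headers. Its test statistic is a likelihood ratio score, per the file headers of the authors' table. Each p-value and FDR in it is the authors', per the file headers. Its sign was settled against the TPM values, and positive means higher in TSA.

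TPM totals hold no depth, but ratios of a gene's TPM values between libraries were ratios of whole numbers. Whole reads could be recovered for 100% of the 27644 genes above 0 in at least 2 libraries, within a relative tolerance of 1e-09. They are the smallest whole numbers that fit the ratios of a gene, so the true reads may be a common multiple of them. A gene above 0 in a single library has no ratio and was given the smallest count. The recovered reads therefore gave a lower bound of the depth of each library. A test of them was added as an alternative after the data were seen. Recovered reads of any pair of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.33 to 95.1, so that no pair was taken for a single library deposited in duplicate.

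Samples were grouped by their labels. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(TPM + 1), for genes at 1 TPM or more in at least 3 of the 6 libraries, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The residual degrees of freedom with the prior came to 6.59. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. A count test was planned only for a table of counts, and the values were TPM. Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment over the 28 lists, and with limma's fry. Numbers of detected genes were compared with a two-sided exact permutation test. Figures were drawn with matplotlib 3.10.9.

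The groups, the main test, the 28 gene lists, the rule for named genes and the settings listed first below were fixed before the data were examined. The rule named the 10 genes with the greatest rise and the 10 with the greatest fall among genes with an approved-style symbol, an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between the groups. It also named up to 4 members of each list with the greatest change among those past the test, or the 2 with the highest mean TPM where fewer than 2 passed, and a set of genes of prior interest whatever their values. Of 479 list entries 469 matched a gene in the table, and NEUROD1, PECAM1, MS4A1, ZEB2, MT1E, MT1M, CTAG1B, SSX2, XAGE1B and SPANXB1 were not analysed here. Results of 2 further genes that the rule names are not reported here.

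Other settings tried were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 TPM, median-of-ratios and quantile scaling, limma without trend and with robust variance, the replicate number as a block, leaving out each library in turn, other detection levels and other bins. Added after the data were seen were fits without both replicate 1 libraries, without mitochondrial genes, with protein-coding genes alone, with the mitochondrial share of reads as a covariate, on recovered reads with limma's voom, and with length and GC trends removed per library. GENCODE 29 served for gene types (94.8% of genes matched), for the length and GC content of the longest transcript and for gene order. It is on another build than hg19, so no coordinates are given.

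The test was checked on simulated TSA and vehicle libraries with 200 changed genes, of which those past the filter were among 16793 tested genes. It recovered 63 of 90 genes changed 2-fold (70%) and 82 of 92 changed 4-fold (89.1%), and 13 of 158 calls (8.23%) were false, above the nominal rate. The simulation changed few genes and drew each gene independently, while 62.2% of the tested genes were called in the real libraries. Its rates therefore need not hold for the real libraries.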

Results

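Messenger RNA was sequenced from H69 cells, a human cell line, after 24 h with trichostatin A (TSA) at 1 µM or with its solvent DMSO (vehicle). TSA inhibits histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The labels do not give the tissue of the line, and the name H69 is in use for more than one human line. Each group held 3 libraries. The treatment tag of the treated samples reads HSA, while the design text and the treatment protocol name TSA, and these samples are called TSA here. Whole reads recovered from the deposited TPM values, which are lower bounds, came to 24400897, 22533307 and 26148651 in vehicle libraries 1, 2 and 3. In TSA libraries 1, 2 and 3 they came to 24803310, 24642000 and 23009041. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

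The comparison asked which transcripts changed in H69 cells after 24 h with TSA. INSM1 (ENSG00000173404.3), a zinc finger transcription factor of neuroendocrine cells, fell from 614 ± 77.4 TPM in vehicle to 24.7 ± 4.93 TPM in TSA (mean ± SD, n = 3 each), a log2 fold change of −4.59 with a standard error of 0.17. DHRS2 (ENSG00000100867.10), a short-chain dehydrogenase/reductase, rose from 0.749 ± 0.319 to 407 ± 15.8 TPM, a log2 fold change of 7.88 with a standard error of 0.14. All 25 genes of a list of G2 and mitosis genes fell. Genes of the unfolded protein and integrated stress responses, antigen presentation genes, pro-apoptotic genes, interferon-stimulated genes and metallothioneins were mostly higher among the members that passed the filter on low values, and most neuroendocrine markers were lower. Of 17596 genes tested with limma, 4929 were higher and 6013 lower in TSA, and 6654 did not pass the test.

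**Figure D1:**
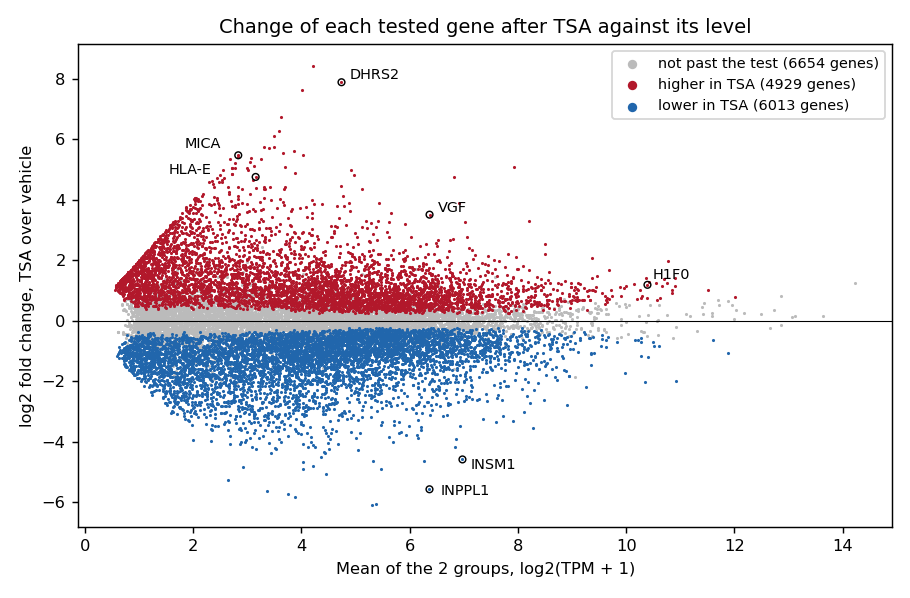
Each point is 1 of the 17596 tested genes, with the log2 fold change of TSA over vehicle against the mean of both groups in log2(TPM + 1) units. Red points (4929) were higher, blue points (6013) lower and grey points (6654) did not pass limma's test, and genes named in the text are circled.

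Among named genes at 5 TPM or more in the higher group and without overlap between the groups, the 10 with the greatest rise were DHRS2, LINC00624, RCN3, ZCCHC12, PCP4L1, ATP1B2, BAIAP3, BLVRB, REEP6 and MICA. LINC00624, a long non-coding RNA, was at 0.142 ± 0.247 TPM in vehicle and 225 ± 53.5 TPM in TSA. RCN3, a calcium-binding protein of the endoplasmic reticulum, reached 91.9 ± 12.9 TPM from 0.371 ± 0.354 TPM. ATP1B2, a beta subunit of the sodium pump, reached 75.6 ± 7.87 TPM, and BLVRB, a biliverdin reductase, reached 84.7 ± 13.4 TPM. MICA, a ligand of the natural killer cell receptor NKG2D, was at 0.0720 ± 0.125 TPM in vehicle and 46.3 ± 4.18 TPM in TSA. The log2 fold changes of the other genes in this set were 5.75 for ZCCHC12, 5.73 for PCP4L1, 5.62 for BAIAP3 and 5.47 for REEP6.

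Among the 10 genes with the greatest fall were TDPX2, RASSF9, LINC00261, INPPL1, SCNN1A, LMO3, MS4A8, H2AFY2 and SYK. INPPL1, an inositol polyphosphate 5-phosphatase, went from 569 ± 59.1 to 10.9 ± 1.09 TPM. SCNN1A, the alpha subunit of the epithelial sodium channel, went from 126 ± 7.32 to 2.75 ± 0.472 TPM, and the tyrosine kinase gene SYK from 80.9 ± 3.24 to 2.26 ± 0.594 TPM. H2AFY2, which encodes a macroH2A histone variant, fell by 4.81 on the log2 scale. The log2 fold changes were −5.84 for RASSF9, −5.74 for LINC00261, −4.91 for LMO3 and −4.91 for MS4A8. TDPX2, at 339 ± 54.3 TPM in vehicle and 4.10 ± 1.41 TPM in TSA, is a processed pseudogene in GENCODE 29, so its reads could not be told from those of its parent gene and its value is uncertain. Over the 20 genes with the greatest rise or fall the adjusted p of limma ran from 5.0e-06 to 1.5e-05.

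Of the called genes, 2728 were at least 2-fold higher and 3472 at least 2-fold lower. In 67.0% of the tested genes the 3 TSA values did not overlap the 3 vehicle values, against 10% by chance for 3 against 3. The median log2 fold change of all tested genes was −0.095, and a median-of-ratios or a quantile scaling moved it by 0.10, so that small changes of either sign are relative to the scaling. Under those scalings 50.1% and 50.4% of the called genes were higher, against 45.0% with TPM as deposited.

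**Figure D2:**
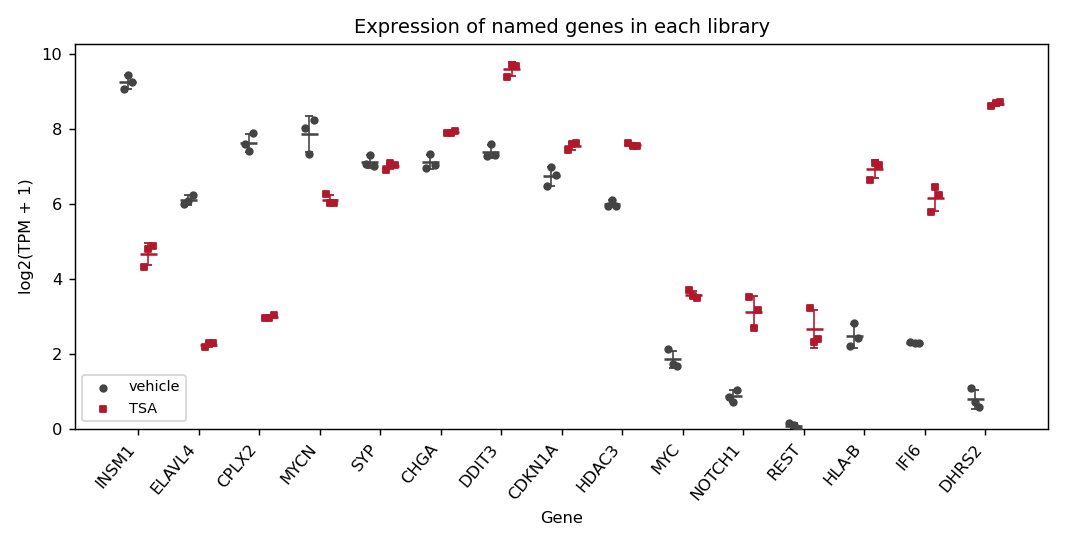
Points show log2(TPM + 1) of named genes in each of the 3 vehicle libraries (dark circles) and the 3 TSA libraries (red squares), with a line at the group mean and bars of 1 SD. INSM1, ELAVL4, CPLX2 and MYCN lay lower in all 3 TSA libraries, and SYP (log2 fold change −0.12, adjusted p 0.37) did not pass limma's test.

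The 28 gene lists fixed before the data were examined held 406 tested entries, of which 148 were higher and 166 lower over all tested genes. Adjusted over the list alone, 150 were higher and 169 lower. Camera, which sets a list against all other tested genes, called 11 lists with its preset correlation of 0.01, 7 higher and 4 lower. With a correlation estimated from these 6 libraries it called 0 of the 28 lists at an adjusted p under 0.05, and 3 at an unadjusted p under 0.05, so each called list below carries both adjusted p-values. Fry, which asks whether the genes of a list move on balance in a single direction and does not compare them with other genes, gave 20 lists with an adjusted p under 0.05. Other groupings of the same 6 libraries into 3 and 3 called up to 13 lists with the preset correlation. Each of these groupings mixes vehicle and TSA libraries and keeps part of the difference between them. Their counts therefore do not show how many lists chance alone would call. The counts of members that passed the test gene by gene are given for each list. A member under 1 TPM in all vehicle libraries was tested only if it reached 1 TPM in all TSA libraries, which raises the share of higher genes in lists with many such members. The camera p-values of these lists include such members and can therefore overstate a rise. Camera was not run without them.

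**Figure D3:**
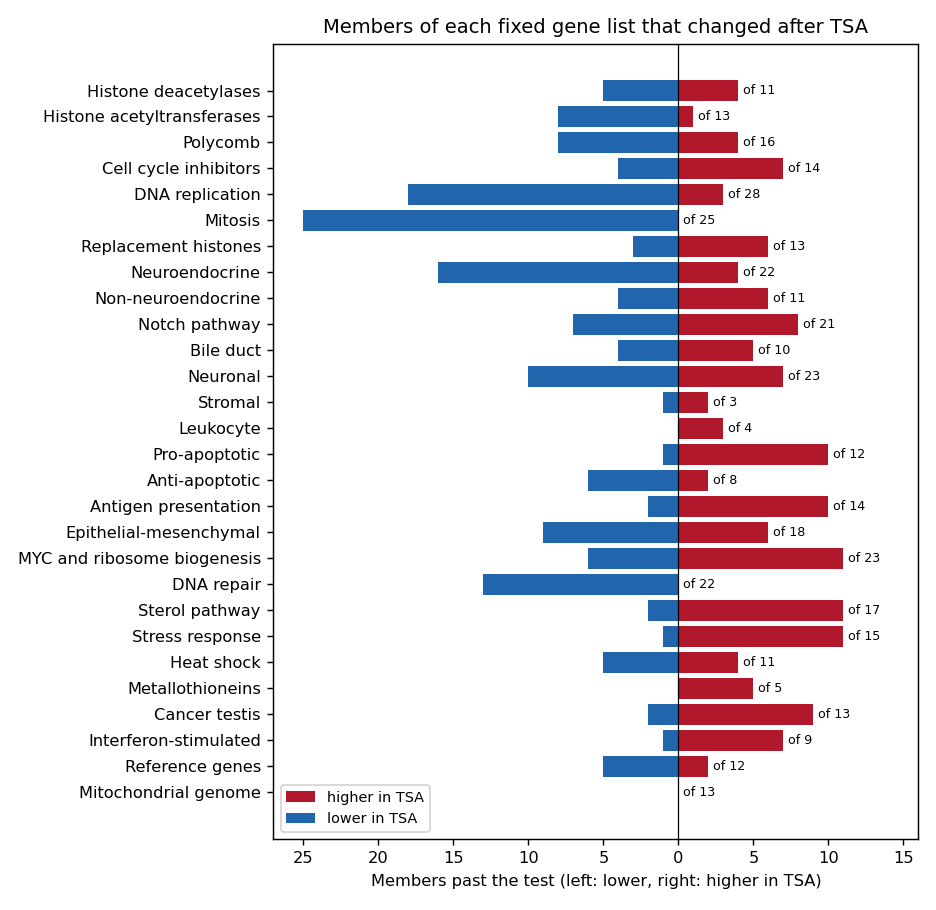
Bars give, for each of the 28 fixed gene lists, how many members were higher in TSA (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05, with the number tested beside them. All 25 mitosis genes were lower and all 5 tested metallothionein genes higher.

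All 25 G2 and mitosis genes fell, each at least 2-fold, with a median log2 fold change of −2.03 (camera adjusted p 5.9e-08, and adjusted p = 0.47 with an estimated correlation). Among them CCNB2, which encodes cyclin B2, went from 248 ± 9.38 to 34.99 ± 9.18 TPM, the spindle protein gene HMMR from 266 ± 14.8 to 39.7 ± 5.02 TPM, and the mitotic kinase gene PLK1 from 146 ± 13.3 to 21.7 ± 5.24 TPM. The proliferation marker MKI67 fell by 3.46 on the log2 scale, with a standard error of 0.57. Of 28 DNA replication and S phase genes 18 were lower and 3 higher (adjusted p 0.0048, and adjusted p = 0.55 with an estimated correlation). TYMS, thymidylate synthase, went from 460 ± 23.9 to 83.8 ± 11.9 TPM and RRM1, a ribonucleotide reductase subunit, from 289 ± 14.3 to 66.0 ± 3.89 TPM, and E2F2 fell by 2.86 on the log2 scale. GINS4, a subunit of the replicative helicase complex, went the other way, from 14.04 ± 2.65 to 57.9 ± 7.04 TPM.

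Of 22 double-strand break repair and Fanconi anaemia genes 13 were lower and 0 higher (adjusted p 0.0067, and adjusted p = 0.39 with an estimated correlation). The log2 fold changes were −2.13 for FANCD2, −1.94 for FANCI, −1.61 for RBBP8 and −1.42 for RAD51D. These genes have long transcripts, with a median annotated length of 4736 nt against 2969 nt over all tested genes with a length, and the libraries differed in how much of the longer transcripts they held. Once length and GC trends were removed from each library, a setting chosen after the data were seen, 11 of the 22 were lower and 1 higher, and the median moved from −0.83 to −0.38.

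Genes that hold back the cell cycle moved both ways. Of 14 cell cycle inhibitor genes 7 were higher and 4 lower, and camera did not call the list (adjusted p 0.61). GADD45B, a stress-induced gene, rose from 4.97 ± 0.651 to 34.9 ± 5.33 TPM. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 107 ± 18.8 to 187 ± 13.2 TPM. CDKN2A fell from 76.2 ± 10.2 to 13.6 ± 1.502 TPM, CDKN2C from 303 ± 30.3 to 65.1 ± 4.32 TPM and CDKN1B from 145 ± 6.97 to 34.1 ± 1.41 TPM. The median log2 fold change of the list was 0.27, while fry gave a downward direction that did not pass its test (unadjusted p 0.16).

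Of 22 tested neuroendocrine markers 16 were lower and 4 higher, or 17 and 4 adjusted over the list alone (camera adjusted p 0.0032, and adjusted p = 0.52 with an estimated correlation). Beside INSM1, the prohormone convertase gene PCSK1 went from 270 ± 17.5 to 17.6 ± 0.835 TPM and the neuronal RNA-binding protein gene ELAVL4 from 68.2 ± 6.31 to 3.75 ± 0.222 TPM. Not all markers fell. CHGA, chromogranin A, rose from 138 ± 18.7 to 239 ± 5.01 TPM, and SYP, synaptophysin, did not pass the test at 140 ± 16.1 and 128 ± 7.65 TPM (adjusted p 0.37, and 0.016 for a log2 fold change of −0.34 once length and GC trends were removed, the lowest of its 21 alternatives, whose highest was 0.998). DLL3, an inhibitory Notch ligand, was at 32.6 ± 4.11 and 21.5 ± 3.90 TPM (log2 fold change −0.59, adjusted p 0.017), a call that ended under a median-of-ratios scaling (adjusted p 0.095), a quantile scaling (adjusted p 0.13), in the test of recovered reads (adjusted p 0.080) and without vehicle replicate 2 (adjusted p 0.053), with 0.0016 to 0.13 over its 21 alternatives. NEUROD1 was not analysed here.

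Of 11 tested markers of non-neuroendocrine, mesenchymal-like or tuft-like tumour cells 6 were higher and 4 lower (adjusted p 0.59), but of the 7 at 1 TPM or more in vehicle 2 were higher and 4 lower. LGALS1, galectin-1, rose from 5.45 ± 1.33 to 115 ± 41.8 TPM. REST, a repressor of neuronal genes, went from 0.0582 ± 0.0571 to 5.57 ± 2.47 TPM and the receptor gene EPHA2 from 0.0240 ± 0.0416 to 5.20 ± 0.525 TPM, while ASCL2 fell from 17.2 ± 1.64 to 1.99 ± 0.486 TPM. VIM and SLFN11 stayed below the filter on low values. VIM was at 0.00948 ± 0.0164 and 0.331 ± 0.116 TPM, and SLFN11 was listed at 0 in all 3 vehicle libraries and at 0.859 ± 0.412 TPM in TSA.

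Of 21 Notch pathway genes 8 were higher and 7 lower (adjusted p 0.73), with a median log2 fold change of −0.075, a mean of 0.088 and a median that turned positive under a median-of-ratios or a quantile scaling. Of the 17 at 1 TPM or more in vehicle 4 were higher and 7 lower. NOTCH1 rose from 0.830 ± 0.210 to 7.92 ± 2.47 TPM, the Notch target HES1 from 14.4 ± 1.08 to 34.8 ± 5.997 TPM and HEYL from 0.392 ± 0.176 to 12.7 ± 0.594 TPM. The ligand gene DLL1 fell from 36.8 ± 3.56 to 3.43 ± 0.468 TPM, and the coactivator gene MAML2 fell by 2.31 on the log2 scale.

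Of 23 neuronal and synaptic genes 7 were higher and 10 lower (adjusted p 0.96), with a median log2 fold change of −0.18 and a mean of 0.018. CPLX2, complexin 2, went from 199 ± 34.5 to 6.92 ± 0.224 TPM and the sodium channel gene SCN3A from 19.8 ± 4.01 to 1.31 ± 0.343 TPM. The neurofilament gene NEFH rose from 2.43 ± 0.827 to 46.3 ± 4.11 TPM, and VGF, a secreted neuropeptide precursor, rose from 23.6 ± 4.64 to 275 ± 25.5 TPM. Of 10 tested bile duct markers 5 were higher and 4 lower, or 5 and 5 adjusted over the list alone (adjusted p 0.95). The list had a median of 0.043 and a mean of −0.11. With length and GC trends removed 4 were higher and 5 lower, with a median of −0.089. Without mitochondrial genes 6 of 11 were higher and 4 lower, with a median of 0.55. KRT19 was at 208 ± 48.2 TPM in vehicle and 101 ± 29.4 TPM in TSA, and KRT7 at 5.43 ± 1.54 and 0.664 ± 0.272 TPM. MUC1 fell by 2.05 on the log2 scale, while SSTR2, a somatostatin receptor, rose by 2.65 and the anion exchanger gene SLC4A2 by 1.49.

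Of 11 histone deacetylase genes 4 were higher and 5 lower (adjusted p 0.94). HDAC3 rose from 63.2 ± 4.18 to 189 ± 5.59 TPM, HDAC1 from 105 ± 10.2 to 180 ± 5.97 TPM and HDAC11 from 1.43 ± 0.275 to 8.86 ± 1.11 TPM. HDAC7 fell from 8.16 ± 1.53 to 0.531 ± 0.0395 TPM and HDAC9 from 14.3 ± 1.397 to 3.06 ± 0.278 TPM. HDAC2 fell from 60.4 ± 1.65 to 34.0 ± 2.57 TPM, a call that ended once length and GC trends were removed (log2 fold change −0.25 with a standard error of 0.25, from −0.81 with 0.090, adjusted p 0.40, the highest of its 21 alternatives, whose lowest was 0.00012). The median of this list was 0.14 and its mean −0.095. Camera gave an upward and fry a downward direction, and neither passed its test (fry unadjusted p 0.28). With length and GC trends removed 4 were higher and 3 lower, and the median was −0.15.

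Of 13 histone acetyltransferase genes 8 were lower and 1 higher, though camera did not call the list (adjusted p 0.086). The coactivator gene NCOA2 went from 33.2 ± 8.89 to 2.81 ± 0.835 TPM, CREBBP from 42.5 ± 14.2 to 9.75 ± 4.46 TPM and KAT5 from 65.1 ± 9.10 to 29.4 ± 2.80 TPM, and KAT6B fell by 1.57 on the log2 scale. Their median annotated transcript length was 7939 nt. With length and GC trends removed, 8 were lower and 2 higher. Of 16 Polycomb genes 8 were lower and 4 higher (adjusted p 0.59), or 5 lower and 4 higher under a median-of-ratios scaling. EZH2, the histone methyltransferase of a Polycomb complex, went from 285 ± 21.3 to 122 ± 24.4 TPM, BMI1 from 103 ± 5.37 to 39.0 ± 2.25 TPM and PCGF2 from 50.8 ± 5.90 to 13.5 ± 1.80 TPM, while JARID2 rose from 20.4 ± 4.45 to 53.0 ± 10.3 TPM. Of 13 replacement or polyadenylated histone genes 6 were higher and 3 lower, or 6 and 1 under a median-of-ratios or a quantile scaling (adjusted p 0.43), with a median of −0.00056 and a mean of 0.30. The linker histone gene H1F0 rose from 888 ± 89.1 to 2032 ± 354 TPM, HIST1H1C from 85.8 ± 14.7 to 321 ± 82.2 TPM and H2AFJ from 15.6 ± 0.544 to 37.0 ± 3.77 TPM. H2AFZ, which encodes H2A.Z, fell from 926 ± 118 to 263 ± 66.8 TPM.

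Of 12 tested pro-apoptotic genes 10 were higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p 0.0058, and adjusted p = 0.39 with an estimated correlation). Of the 10 tested members at 1 TPM or more in vehicle 8 were higher and 1 lower. TNFRSF10B, a receptor for the ligand TRAIL, went from 0.0290 ± 0.0503 to 16.4 ± 6.53 TPM, BBC3 from 1.88 ± 0.289 to 14.9 ± 3.09 TPM and BMF from 5.44 ± 0.385 to 29.2 ± 3.51 TPM. BID, the member that was lower, went from 24.7 ± 2.04 to 1.97 ± 0.0798 TPM. Of 8 tested anti-apoptotic genes 6 were lower and 2 higher (adjusted p 0.072, and 0.036 under a median-of-ratios scaling, with 0.014 to 0.60 over its 22 alternatives). BCL2 fell from 24.9 ± 1.42 to 4.17 ± 0.834 TPM and BCL2L1 from 120 ± 10.0 to 33.3 ± 0.116 TPM, CFLAR fell by 2.53 on the log2 scale and XIAP fell by 1.51.

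Of 15 genes of the unfolded protein and integrated stress responses 11 rose and 1 fell, or 11 and 0 under a median-of-ratios scaling (camera adjusted p 0.0015, and adjusted p = 0.52 with an estimated correlation). DDIT3, a transcription factor of that response, rose from 168 ± 22.0 to 777 ± 96.0 TPM, ATF3 from 10.1 ± 0.927 to 60.4 ± 5.03 TPM, SESN2 from 7.94 ± 0.337 to 38.3 ± 1.29 TPM and CHAC1 from 0.480 ± 0.157 to 11.2 ± 0.551 TPM. All 5 tested metallothionein genes, which encode metal-binding proteins, were higher (adjusted p 0.011, and adjusted p = 0.46 with an estimated correlation). Of them 3 were at 1 TPM or more in vehicle. MT1X rose from 5.996 ± 3.94 to 89.7 ± 25.9 TPM, MT3 from 0.782 ± 0.190 to 9.33 ± 0.831 TPM and MT1F from 8.10 ± 0.761 to 16.95 ± 1.37 TPM, and MT1G was listed at 0 in vehicle and at 1.59 ± 0.443 TPM in TSA. Heat shock genes went both ways, with 4 of 11 higher and 5 lower, or 4 and 3 under a median-of-ratios scaling (adjusted p 0.86), a median of −0.45 and a mean of 0.18. BAG3 rose from 0.788 ± 0.314 to 10.5 ± 0.346 TPM, HSPA1A from 52.9 ± 10.6 to 135 ± 5.18 TPM and DNAJB1 from 105 ± 6.78 to 243 ± 35.1 TPM, while HSPH1 fell from 275 ± 18.3 to 104 ± 9.50 TPM. HSPA1A and its near-identical copy share reads, so its value is uncertain.

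Of 14 tested antigen presentation genes 10 were higher and 2 lower (camera adjusted p 0.0055, and adjusted p = 0.48 with an estimated correlation). The other 6 genes of this list in the table were below the filter, and of the 9 tested members at 1 TPM or more in vehicle 5 were higher and 2 lower. The class I genes HLA-B and HLA-E rose from 4.66 ± 1.28 to 122 ± 20.4 TPM and from 0.709 ± 0.123 to 45.3 ± 7.38 TPM, and HLA-F rose by 2.41 on the log2 scale. Reads can be shared between class I genes, so the split between them is uncertain. ERAP1, which trims peptides for class I molecules, fell from 12.2 ± 1.74 to 0.901 ± 0.138 TPM. Of 9 tested interferon-stimulated genes 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone (camera adjusted p 0.0060, and adjusted p = 0.39 with an estimated correlation). The other 11 of the 20 listed genes stayed under 1 TPM on average in both groups and were not tested, and of the 7 tested members at 1 TPM or more in vehicle 5 were higher and 1 lower. IFI6 rose from 3.92 ± 0.0580 to 71.4 ± 16.3 TPM, IRF7 from 3.14 ± 0.350 to 25.6 ± 3.70 TPM, and ISG15 from 1.61 ± 0.690 to 16.2 ± 5.41 TPM, and BST2 rose by 1.49 on the log2 scale.

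Of 13 tested cancer testis antigen genes 9 were higher and 2 lower (camera adjusted p 0.022, and adjusted p = 0.48 with an estimated correlation), a call that ended with a filter of 5 TPM (adjusted p 0.23) and with length and GC trends removed (adjusted p 0.062), with 0.010 to 0.48 over its 22 alternatives. The filter left 9 members, 5 higher and 2 lower, and took the median log2 fold change from 1.30 (quartiles 0.092 and 1.99) to 0.62 (0.020 and 1.60), while without length and GC trends 9 were still higher and 2 lower, with a median of 1.39 (0.040 and 1.98). Of the 10 tested members at 1 TPM or more in vehicle 6 were higher and 2 lower. MAGEB2 rose from 1.38 ± 1.11 to 25.6 ± 4.92 TPM, MAGEA1 from 1.08 ± 0.0796 to 7.31 ± 1.18 TPM, PAGE1 from 0.451 ± 0.390 to 6.18 ± 1.84 TPM and MAGEA4 from 0.115 ± 0.0749 to 4.10 ± 1.33 TPM. MAGEA family members are similar in sequence, so reads shared between them make single values uncertain. Of 17 tested sterol and LDL receptor pathway genes 11 were higher and 2 lower (adjusted p 0.022, and adjusted p = 0.62 with an estimated correlation). SREBF1, a transcription factor of lipid synthesis, rose from 8.47 ± 2.11 to 38.0 ± 3.33 TPM, MVK, mevalonate kinase, from 8.90 ± 1.048 to 28.1 ± 2.85 TPM, FDFT1 from 133 ± 28.6 to 284 ± 9.70 TPM and LSS from 21.6 ± 3.86 to 47.7 ± 5.24 TPM.

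Among 23 genes of the MYC family and of ribosome biogenesis 11 were higher and 6 lower (adjusted p 0.21). MYCN fell from 241 ± 73.1 to 67.9 ± 6.95 TPM, while MYC rose from 2.63 ± 0.622 to 10.99 ± 0.885 TPM, MYCL from 0.126 ± 0.0863 to 2.27 ± 0.684 TPM and their partner MAX from 31.8 ± 4.39 to 95.7 ± 6.90 TPM. Of 18 tested genes of the epithelial and mesenchymal transition 6 were higher and 9 lower, or 6 and 10 adjusted over the list alone (adjusted p 0.44), and of the 15 at 1 TPM or more in vehicle 3 were higher and 9 lower. The cell adhesion gene CDH1 rose from 18.3 ± 1.397 to 66.2 ± 0.720 TPM. The splicing regulator gene ESRP1 fell from 204 ± 13.2 to 30.3 ± 1.501 TPM, TGFB2 from 29.9 ± 3.29 to 2.76 ± 0.694 TPM, TWIST1 from 46.5 ± 5.55 to 11.2 ± 2.48 TPM and CLDN3 from 20.2 ± 3.42 to 4.29 ± 1.396 TPM.

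Of 12 genes often used as references 2 were higher and 5 lower (adjusted p 0.96), or 3 and 1 under a median-of-ratios scaling, with a median of 0.0054 and a mean of −0.077. SDHA rose from 59.2 ± 5.84 to 140 ± 6.46 TPM and ACTB, beta-actin, fell from 1857 ± 420 to 819 ± 198 TPM. RPLP0 was at 644 ± 90.1 and 1057 ± 195 TPM (adjusted p 0.015, and 0.052 without vehicle replicate 1, 0.062 without vehicle replicate 3, 0.053 without TSA replicate 2 and 0.061 without TSA replicate 3, with a lowest of 0.00015 over its 21 alternatives). YWHAZ was at 632 ± 73.6 and 395 ± 52.6 TPM (adjusted p 0.0067, and 0.061 under a median-of-ratios scaling and 0.22 with length and GC trends removed, with a lowest of 0.00021 over its 21 alternatives).

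Of 7 tested markers of stromal cells and leukocytes 5 were higher and 1 lower in TSA, and 16 others in the table were below the filter. Only 3 of the stromal markers passed the filter, of which 2 were higher and 1 lower, or 1 and 1 of the 2 at 1 TPM or more in vehicle (adjusted p 0.59). COL1A1 was at 0.510 ± 0.358 and 5.44 ± 0.958 TPM, THY1 at 6.51 ± 1.31 and 13.8 ± 1.86 TPM and POSTN at 2.998 ± 1.62 and 0.168 ± 0.0152 TPM. Of 4 tested leukocyte markers 3 were higher and 0 lower, or 1 and 0 of the 2 at 1 TPM or more in vehicle (adjusted p 0.095), with CD68 at 1.14 ± 0.513 and 3.88 ± 1.11 TPM and CSF1R at 0.00914 ± 0.0158 and 1.22 ± 0.160 TPM. None of the 13 mitochondrial protein-coding genes passed limma's test (0 at an adjusted and 0 at an unadjusted p under 0.05, 0 in the limma-voom test of recovered reads, camera adjusted p 0.70), with MT-CO2 at 12210 ± 5103 and 13326 ± 5246 TPM and MT-CO3 at 8607 ± 4432 and 9275 ± 4357 TPM. The share of reads from the mitochondrial genome differed more within the groups than between them, at 3.09%, 1.26% and 2.504% in vehicle libraries 1 to 3 and 5.08%, 2.32% and 3.22% in TSA libraries 1 to 3.

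The next comparison asked whether TSA changed how many genes were expressed. Vehicle libraries held 16607 ± 525 genes at 1 TPM or more and TSA libraries 16969 ± 856 (n = 3 each), a difference of 362 genes that lay within the spread between libraries (exact permutation test, two-sided, p 0.6, where 3 against 3 cannot go below 0.1). Without TSA replicate 1 the difference was −127.5. At 0.1 TPM or more the difference was 1471 genes (exact p 0.2), and at 5 TPM or more it was −182 (exact p 0.7).

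Change was also set against the level in vehicle, with genes binned by vehicle library 1 and the change taken from the other vehicle libraries. Genes at high levels in vehicle were lower in TSA at the median, with a median log2 fold change of −0.39 over the 2028 tested genes at 100 TPM or more in vehicle library 1, −0.28 over the 4200 genes at 30 to 100 TPM and −0.16 over the 4231 genes at 10 to 30 TPM. Binning by vehicle library 3 gave −0.36, −0.29 and −0.20 in the same order, while binning by vehicle library 2 gave no such gradient, at −0.25, −0.27 and −0.29. With genes binned by TSA library 1 instead, the 1841 genes at 100 TPM or more in it were lower in vehicle, with a median of −0.29, while the medians were −0.013 for the 4080 genes at 30 to 100 TPM and 0.23 for the 4366 genes at 10 to 30 TPM. The 944 tested genes at 0.1 to 1 TPM had a median of 1.34 and the 443 under 0.1 TPM a median of 1.65, but the filter on low values favours genes of these bins that are higher in TSA. Over all genes in the table the medians of those bins were 0.050 and 0.079.

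**Figure D4:**
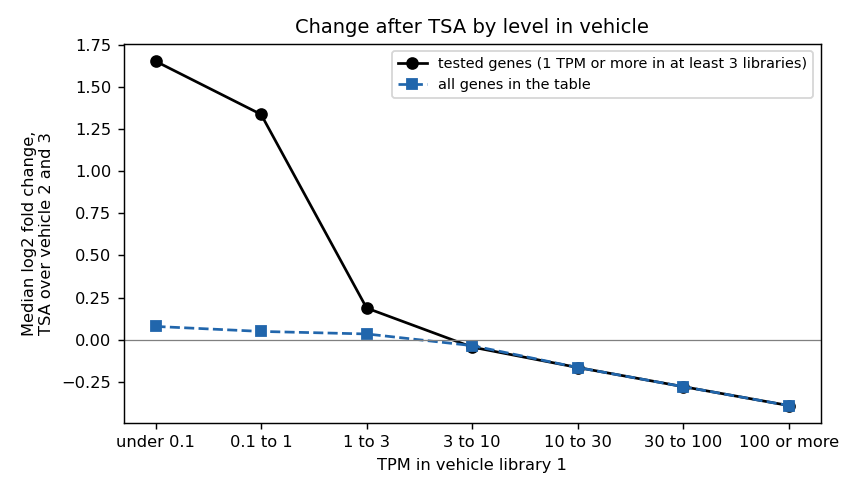
Lines give the median log2 fold change of TSA over vehicle libraries 2 and 3 for genes in 7 bins of TPM in vehicle library 1, for tested genes (black circles) and for all genes in the table (blue squares, dashed). Both lines fall to −0.39 at 100 TPM or more, and below 1 TPM they part, at 1.34 and 0.050 for 0.1 to 1 TPM.

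The fold changes were last set beside the authors' deposited table of a likelihood ratio test of the same samples. The log2 fold change in the authors' deposited table was positive for 6925 and negative for 6202 genes at a false discovery rate under 0.05, where positive means higher in TSA. Among genes tested here, 9869 were called in both analyses with the same sign and 0 with opposite signs, 1073 were called here alone and 475 in the authors' deposited table alone. A further 2783 genes called in the authors' deposited table were below the filter used here. Across the 17596 genes the log2 fold changes had a Pearson r of 0.92 and a Spearman rho of 0.99, and genes are not independent replicates. For INSM1 the authors' deposited table gives a log2 fold change of −4.55, and for DHRS2 9.16.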

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

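The tests that left out both replicate 1 libraries, removed mitochondrial genes, kept protein-coding genes alone, took the mitochondrial share as a covariate, used recovered reads or removed length and GC trends were chosen only after the result was seen. Across all settings no gene called in 1 direction was called in the other. Leaving out each library in turn gave 4289 to 4977 higher and 5157 to 6585 lower genes, a filter of 5 TPM gave 3788 and 4956, no filter gave 5826 and 6170 of 31814 genes, and recovered reads gave 5524 and 5333. Of 2831 alternatives for 136 named genes, 2817 kept the direction and the side of the threshold, 11 lost the call, 1 gained it and 2 reversed. The log2 fold change of MT-CO2 (−0.50) and the log2 fold change of MT-CO3 (−0.61) reversed with the mitochondrial share as a covariate, which removes what these genes share by construction. The calls lost were those of DLL3, RPLP0, YWHAZ and HDAC2, the call gained that of SYP, and the cause was not tested. For single lists 589 of 611 alternatives kept the call. With an estimated correlation camera called 0 lists higher and 0 lower, in place of 7 and 4. Beyond that only the cancer testis list lost its call, and the anti-apoptotic, acetyltransferase, epithelial-mesenchymal and non-neuroendocrine lists gained 1 in some settings. Among tested genes, the median change at 0.1 to 1 TPM lay 1.73 above that at 100 TPM or more. It lay 2.91 above it with a pseudocount of 0.1, which enlarges changes of low genes by construction. Over all genes in the table those medians were 0.050 and −0.39 with the main pseudocount. The filter favours low genes that are higher in TSA. The replicate block gave 5637 higher and 6848 lower genes and the same number of called lists, but the labels do not say that the numbers pair libraries. Deviations of libraries with the same number correlated at 0.63, 0.59 and −0.07 across genes, and vehicle 3 correlated better with TSA 1 (0.11) than with TSA 3, so the numbers are at most a hint of shared handling. The planned DESeq2 alternative was not run, since it was meant for counts. Genes of few reads limit precision, as with MICA and LINC00624, each with 2 reads over the vehicle libraries.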

Other observations

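All tests in this part were chosen only after the result was seen, and some were revised after a first value. Beyond the fixed lists, 18 gene families were examined and 4 are described. Of 84 ribosomal protein genes, paralogs included, 46 were higher and 5 lower in TSA (camera adjusted p 2.5e-05, and adjusted p = 0.99 with an estimated correlation). Their median log2 fold change was 0.57. RPL28, with a rise well above that median, was at 95.6 ± 20.3 TPM in vehicle and 302 ± 70.6 TPM in TSA (mean ± SD of 3 libraries each). Of 18 subunits of the vacuolar proton pump 14 were higher and 1 lower (adjusted p 0.00034, and adjusted p = 0.80 with an estimated correlation). Their median log2 fold change was 0.84, and ATP6V0D1 rose from 18.4 ± 4.08 to 70.4 ± 14.1 TPM. Of 18 centromere protein genes 16 were lower and 0 higher (adjusted p 0.00032, and adjusted p = 0.16 with an estimated correlation). Their median log2 fold change was −1.07, and CENPL fell from 42.2 ± 1.67 to 10.6 ± 0.360 TPM. CENPE and CENPF of this family are also in the G2 and mitosis list, so the family is not independent of that list. The directions of these families held under each scaling tried.

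The HOX genes, transcription factors of body patterning that lie in clusters, were mostly lower in TSA. Of 28 tested, 24 were lower and 4 higher (camera adjusted p 0.00016, and adjusted p = 0.16 with an estimated correlation). All 24 tested genes of groups 1 to 11 fell, such as HOXC6 from 29.9 ± 2.11 to 1.503 ± 0.416 TPM, and all 4 tested genes of groups 12 and 13 rose, HOXC13 from 1.18 ± 0.336 to 21.5 ± 3.30 TPM and HOXB13 from 0.259 ± 0.0384 to 6.89 ± 0.457 TPM, with HOXA13 and HOXC12 rising by 2.09 and 1.27 on the log2 scale.

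This division was drawn from the values of the same genes, and none of the 6 genes of groups 12 and 13 was at 1 TPM or more in all 3 vehicle libraries, so that a member entered the test only if it reached 1 TPM in a TSA library too, and no p-value is given for the division. The part played by that filter cannot be told apart from a response of these groups, since of the 2 untested genes 1 lay higher (HOXD13, 0 against 9 reads) and HOXD12 lower (33 against 9 reads). The part of a general rise of genes at low levels cannot be told apart either, since 1 of 8 genes of groups 1 to 11 under 2 TPM lay higher in TSA, against 5 of 6 in groups 12 and 13, but all 8 were below the filter. The test of the filter was first read as favouring it and the test of low levels as arguing against a general rise, and both were then read as undecided, because they rest on few reads. A response to TSA that differs by paralog group stays open as a hypothesis, while the fall of the 24 tested genes of groups 1 to 11 does not rest on the filter.

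The second principal component (12.5% of variance) spread the libraries within groups, at 29.5, −36.5 and 3.07 in vehicle libraries 1, 2 and 3 and 52.2, −31.6 and −16.7 in TSA libraries 1, 2 and 3, so that library 2 lay farthest from the others in vehicle and library 1 in TSA, and the deviations of vehicle 1 and TSA 1 from their group means correlated at 0.63 across genes, which are not independent replicates. Mitochondrial transcripts alone do not account for that correlation, which was 0.61 without them. It was 0.58 once length and GC trends were removed, so these trends, as fitted on the longest annotated transcript, are not the whole cause. Trends with the length of the transcripts that the cells express could remain after this removal. Whether length-dependent recovery of transcripts is part of the cause cannot be told apart, because the correlation with transcript length of library 1 minus another library was 0.55 against vehicle 2 but 0.077 against vehicle 3, with 0.57 and 0.60 against TSA 2 and 3. More unspliced or nuclear RNA may be part of it, as the share of reads in sense intronic genes was 1.65 times the mean of the other libraries in vehicle and 2.09 times in TSA, above each of them. No biological explanation was tested.

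Of 1491 protein-coding genes without a read in vehicle, 89 reached 1 TPM or more in TSA, led by TNFSF9 at 15.9 ± 4.95 TPM and TCEAL5 at 15.8 ± 2.68 TPM, while 2 of the 260 genes without a read in TSA reached that level in vehicle. Deeper sequencing is argued against by a ratio of total recovered reads of 0.991. Of the silent genes 62.2% stayed under 0.1 TPM in TSA. This does not decide on background reads from unspliced RNA or DNA, since low or uneven background would leave many genes there too. Stromal cells or leukocytes among the treated cells are argued against by their abundant transcripts, of which 1 of 8 (COL1A1, 5.44 ± 0.958 TPM) reached the median of 1.75 TPM of the genes that rose, with COL1A2 at 0.255 and VIM at 0.331 TPM. That test replaced an undecided one, in which 6 of 23 fixed markers of these cells were at 1 TPM or more in TSA. Induction by TSA was not tested on its own, and transcription that runs in from neighbouring genes was not examined, so the source of the rise stays open.

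The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping called 10942 genes and 6200 at least 2-fold changed genes, each the highest in 1 of 10 groupings, and the highest of the others was 0 for both, but the others mix vehicle and TSA libraries, so that the difference between the groups enters their spread and a 0 decides nothing. It called 11 lists with camera, a number that 4 of the 10 groupings reached, and the highest of the others was 13. The other groupings keep part of the difference between vehicle and TSA. Their list counts therefore do not show how many lists chance alone would call.

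Longer transcripts were lower in TSA across 13049 protein-coding genes, with a Spearman correlation between log2 fold change and length of −0.15. The medians were 0.095 in the shortest and −0.39 in the longest of 5 classes of length. The libraries of the groups overlapped in their correlation with length (exact permutation test, two-sided, p 0.2). With 3 against 3 this test cannot go below 0.1, so it does not decide on the trend. The change correlated negatively with length in 8 of 9 pairs of a TSA and a vehicle library, which share libraries. Across the same genes the Spearman correlation between log2 fold change and GC content was 0.17. Log2 fold changes of neighbouring genes along the chromosomes correlated at 0.15, against a highest value of 0.033 in 10000 shuffles of gene order (permutation p 1e-04, the smallest they can give), and at 0.029 for genes 20 places apart, across genes that are not independent replicates. Whether GC content plays a part in this correlation was not tested.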
